A study of Mus musculus with 23 samples.

How the data were processed

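Expression was measured on 23 Affymetrix-type mouse arrays, 1 per clonal preadipocyte line, from biotin-labelled RNA with 250 ng of total RNA as starting material, per the labels' protocols. The deposited values are on a log2 scale, from 2.03 to 14.46, with a median of 5.13 over the whole table. The log2 scale was read from the range and shape of the values, since no header states it. Per the submitters' processing notes, the software was MAS5, with no version given; how the arrays were summarised, scaled and brought to nearly equal medians is not given in the sources used here. Array medians lay between 5.09 and 5.16, so the values were used as deposited. An offset foreseen for linear values was not needed.

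Of 45101 probe sets, 64 were controls. A single gene symbol was listed for 34958, several for 932 and none for 9211 (51 of these are controls); probe sets with several symbols named no gene. Symbols came from the platform annotation, and 34754 of the single-symbol probe sets were matched by Entrez ID to the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and left 204 unmatched under the annotation's symbol. That table was used for names and for the chromosome of each gene. Each of the 18193 genes was represented by the probe set with the highest mean over all lines. Genes above the table median in at least 3 lines were tested, which left 12307. Among the genes named by the rule given below and those that differed from both other types, 74 have several probe sets. For 4 of them (Shox2, Gata6, Arhgef17 and Zfp106) another probe set had the opposite sign in 1 comparison. Single genes picked outside the rule were not in this check. With all probe sets tested, some genes named as passing did not pass in each. Examples are Ldah in Type 2 (1 of 3 passed), Ror2 and Fkbp11 in Type 3 (1 of 2 each) and S1pr3 in Type 1 (2 of 3). No detection calls were used here, and the number of arrays limits the precision. The spiked bacterial controls averaged 8.85 for BioB and 13.7 for Cre, a span of 4.81. The correlation of array pairs ran from 0.937 to 0.992, and 0 pairs held identical values.

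Groups were taken from the labels: Type 1 (3 lines), Type 2 (5), Type 3 (8) and Other (7). Replicate numbers follow the order of deposition and only name a line. The depot of origin was read from the clone name, which begins with SCF in 12 lines and PGF in 11, taken as the subcutaneous and perigonadal fat of the design text. A differentiation score and a media acidification score, each from 1 to 4, are given per line; the direction of the acidification score and whether the RNA came from undifferentiated or differentiated cells are not given in the sources used here.

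Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, over all 23 lines with 1 shared estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were each type minus the mean of the other types, Other minus the mean of the 3 types, PGF minus SCF with group in the model, and the slope per point of each score. Both pairwise contrasts between types were read from the same fit. The groups had been formed by the submitters through clustering of expression data, per the labels, so p-values between types describe the groups and are not independent evidence that they exist. All lines came from 1 mouse, so p-values measure the spread between clones.

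The 25 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. A list score is the mean of a list's gene-centred log2 values in a line. Scores between groups were compared by exact two-sided permutation tests, between depots and in correlations by 100000 permutations, and type by depot with Fisher's exact test. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these and for the plots. The comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. For each type contrast the rule names the 8 genes with the largest difference in each direction among those that passed, leaving out clone and predicted names, and for Other the 5. Where none passed, as for depot and the scores, it names the 3 smallest p-values in each direction. Wt1, Tagln and Mx1 are named in each type contrast, the patterning genes for depot, and up to 4 members of each list that passed. Genes that differed from both other types, and single genes outside the rule, were picked after the values were seen.

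The scripts were tested on simulated data built on the 12307 genes with 100 genes changed at each size. At a 2-fold change 88% were recovered for Type 1, 86% for Type 2, 89% for Type 3, 90% for Other and 89% for depot. At 4-fold these shares were 94%, 97%, 99%, 99% and 99%. For a slope of 1.41-fold per point, 87% were recovered for the differentiation score and 96% for acidification. The simulated genes were independent, with noise from the spread within groups and no group differences other than planted ones. The score fits have no group term, so differences between types widen their real spread. The shares for the scores are therefore likely too high. False calls made up 3.1% to 6.6% of the calls.

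Alternatives were quantile normalisation, centring of each array on its median, other filters, the mean of a gene's probe sets, all 24830 probe sets that passed the filter, an intensity trend, array weights, depot or the number in the clone name in the model, fewer groups in the fit, a 2-fold minimum and leaving out each line in turn. Leaving out the 3 Type 1 lines for Other and for the scores, requiring both pairwise contrasts, the clone number and an offset of 13.16 on the linear scale were added after seeing the data.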

Results

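Clonal preadipocyte lines were compared, each grown from a single sorted cell of the stromal vascular fraction, the non-fat cell fraction of adipose tissue. The cells came from subcutaneous and perigonadal fat of 1 male Immortomouse aged 8 weeks, a strain whose cells carry a temperature-sensitive viral antigen that lets them divide in culture. Of 190 cells sorted after 2 passages, 23 lines are analysed here, which had been cultured in medium holding interferon gamma (10 units/mL) at 33 °C. All 3 Type 1 lines were PGF, Type 2 held 4 SCF and 1 PGF lines, Type 3 held 4 of each, and Other, the lines given no numbered type, held 4 SCF and 3 PGF lines. Over the 16 lines of the 3 types, an association of type with depot did not pass in Fisher's exact test (p = 0.13, two-sided). With so few lines this does not exclude one. Levels are log2 signal, errors beside means are SD over lines and errors beside differences are SE.

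The first question was what set the Type 1 lines apart. They carried high levels of genes of mesothelium, the cell layer that covers visceral organs and visceral fat. Wt1, a transcription factor of that layer, averaged 10.55 ± 0.13 (n = 3) against 3.30 ± 0.27 in Type 2 (n = 5) and 3.71 ± 0.71 in Type 3 (n = 8), a difference of 7.05 ± 0.33 (133-fold, adjusted p = 2.67e-13, limma). In all 3 Type 1 lines Wt1 lay between 10.40 and 10.64, above the highest of the 20 other lines at 5.24. Rises of similar size were measured for the keratin Krt18 (8.19 ± 0.39), the uroplakin Upk3b (7.85 ± 0.36), Lrrn4 (8.07 ± 0.20), the kinase Stk26 (8.44 ± 0.41), Lratd2 (7.25), the growth factor Bmp4 (7.19) and Cd200 (7.06), each with all 3 lines above every other line. Of the 15 mesothelial genes tested, 12 rose and 0 fell; adjusted over the list alone, 12 rose and 2 fell. Rspo1 rose by 5.98 and Upk1b by 6.45. The list passed in camera (adjusted p = 1.15e-12) and also with an estimated correlation (adjusted p = 0.0284). It holds Wt1, which the study chose as a marker on these lines.

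Transcripts abundant in the other lines were low in Type 1. The fibroblast growth factor Fgf7 averaged 5.98 ± 1.68 in Type 1 against 11.67 ± 0.24 in Type 2 and 11.68 ± 0.28 in Type 3, a difference of -5.70 ± 0.38 (adjusted p = 1.21e-10). S1pr3, a receptor for sphingosine 1-phosphate, differed by -5.55, Plpp3 by -5.54, Pla1a by -5.50, Sned1 by -5.50, Ampd3 by -5.44, Sncg by -5.44 and Galnt13 by -5.21, and each was lower in all 3 lines than in any other line. Among genes below both other types were also the collagen Col6a3 (-5.08), the peptide hormone precursor Adm (-5.09) and Ebf1 (-5.03), a transcription factor of the fat cell lineage. Of 17 tested genes of adipocyte differentiation, 2 rose and 6 fell, and adjusted over the list alone the counts were 2 and 6. Those that fell included Pparg (-3.67 ± 0.43) and Cebpa (-3.23 ± 0.50), the central regulators of fat cell formation, and Fabp4 (-4.70 ± 0.76); Pparg and Cebpa were picked as examples after their values were seen. The list as a whole did not pass (camera adjusted p = 0.178). The subcutaneous-type patterning list had 0 higher and 3 lower of 5 (adjusted p = 0.101), extracellular matrix 1 and 9 of 27 (adjusted p = 0.178), and smooth muscle contractile 6 and 1 of 16 (adjusted p = 0.178); adjusted over each list alone these were 0 and 3, 1 and 9, and 6 and 2. With fry the adipocyte differentiation (adjusted p = 0.00502), subcutaneous-type patterning (adjusted p = 1.56e-06) and extracellular matrix lists (adjusted p = 0.00428) passed as lower.

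In all, 4042 of 12307 genes changed in Type 1 (2240 higher, 1802 lower). With each array centred on its median the split was 1761 higher and 2416 lower. Of the 4042, 2616 differed from both other types in the same direction (1501 higher, 1115 lower). The smooth muscle gene Tagln rose by 3.48 ± 0.80 (adjusted p = 0.00192), with 2 of 3 lines above every other line, and Mx1, an interferon-induced antiviral gene, did not pass (1.14 ± 1.01, adjusted p = 0.409). In camera, the lists for other cell types did not pass in Type 1. The adjusted p was 0.473 for macrophage and leukocyte, 0.677 for endothelial, 0.677 for pericyte, 0.495 for epithelial and 0.234 for skeletal muscle genes. With fry the endothelial list passed as higher (adjusted p = 0.00989), and the macrophage and leukocyte (adjusted p = 0.0202) and skeletal muscle lists (adjusted p = 0.000941) as lower. The actin 3' minus 5' signal, a sign of RNA integrity, was 1.58 in Type_1 1 and between 0.53 and 1.00 in the other lines. Because all 3 lines are PGF, depot and type are partly confounded; with depot in the model 3363 genes passed.

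**Figure D1:**
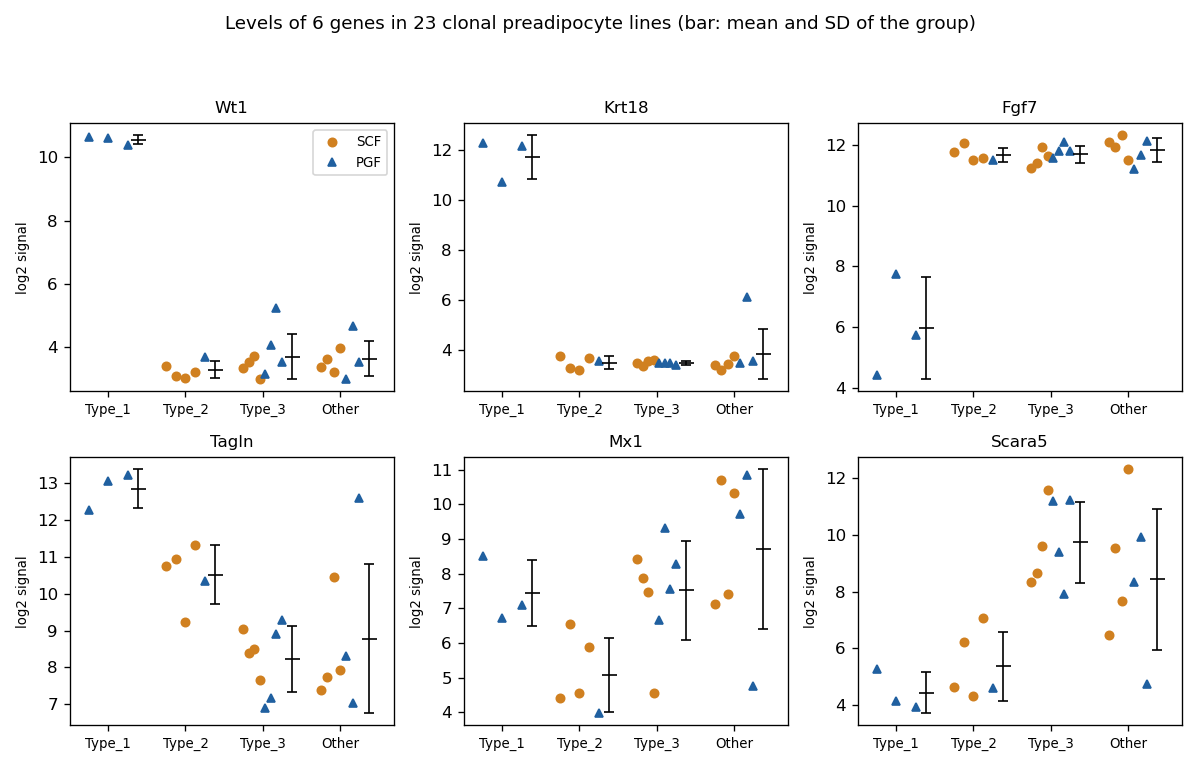
Each point is the log2 signal of 1 gene in 1 clonal line, for 6 genes in separate panels with the 4 groups on the horizontal axis; orange circles are SCF lines, blue triangles PGF lines, and the bar gives the mean and SD of the group. The 3 Type 1 lines lie above all others for Wt1 and Krt18 and below all others for Fgf7, while Tagln, Mx1 and Scara5 overlap between groups.

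The Type 2 lines had the highest mean of Fabp4, a fatty acid carrier of the fat cell lineage, at 9.07 ± 1.31 (n = 5) against 7.64 ± 1.18 in Type 3 and 3.66 ± 0.69 in Type 1. Against the mean of the other types it rose by 3.42 ± 0.66 (adjusted p = 0.00136), as did the aldehyde dehydrogenase Aldh1a7 (3.59, adjusted p = 0.000925), the serpin Serpinb9g (3.98, adjusted p = 0.00953), the glutamate transporter Slc17a6 (2.87), Sncg (2.85), Fgf7 (2.84) and Ltbp1 (2.83). For Fgf7, Sncg and Ltbp1 this comes from low Type 1 values, since Type 2 minus Type 3 was -0.02, 0.18 and 0.43 and did not pass (adjusted p = 0.988, adjusted p = 0.911 and adjusted p = 0.598). The other 4 did not pass against Type 3 alone either: Fabp4 1.44 (adjusted p = 0.269), Aldh1a7 2.73 (adjusted p = 0.0716), Serpinb9g 3.40 (adjusted p = 0.108) and Slc17a6 2.53 (adjusted p = 0.0908). The proteoglycan Dcn was lower, at 5.29 ± 0.63 against 12.25 ± 1.05 in Type 1 and 7.23 ± 2.39 in Type 3 (-4.45 ± 1.03, adjusted p = 0.00642), as was Igfbp3 (-4.06, adjusted p = 0.00158). Both are high in Type 1, and neither is among the 9 genes below that differed from both other types. Dcn lay at 12.72 in Type_3 4 and from 4.81 to 7.62 in the other Type 3 lines. Of 5 Type 2 lines, 1 lay below every line of the other groups for Dcn and 0 for Igfbp3. The remaining genes named by size, Stk26 (-4.25), Krt18 (-4.08), Lrrn4 (-4.02), Upk3b (-3.89), Wt1 (-3.83) and Bmp4 (-3.80), are those raised in Type 1.

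In Type 2 the leukocyte surface gene Cd53 passed narrowly (2.93 ± 0.94, adjusted p = 0.0479). It no longer passed in each of 14 refits that left out 1 line: Type_3 1, 2, 4, 5, 7 or 8, Other 2 or 3, Type_2 1, 2, 3 or 5, or Type_1 1 or 3 (adjusted p from 0.0501 to 0.135). Nor did it pass with depot (adjusted p = 0.09) or the clone-name number in the model (adjusted p = 0.0826), without a filter on low values (adjusted p = 0.0616), with the mean of its probe sets (adjusted p = 0.0611) or with an offset (adjusted p = 0.0513).

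Altogether 1353 genes changed in Type 2 (539 higher, 814 lower; 758 and 650 with each array centred on its median). Without the line Type_1 1 the count was 889. Of these, 9 differed from both other types in the same direction, a set that rests on the Type 2 minus Type 3 calls, which fell from 47 to 0 without Type_2 1 and are given by left-out line below. The extracellular matrix gene Mamdc2 (1.58 ± 0.24), Dok1 (0.92), Wdr36 (0.57), Foxn2 (0.52), Thoc6 (0.46) and Ldah (0.38) were higher. The phosphatase Ptpn13 (-1.75 ± 0.19, adjusted p = 2.10e-06), Pcdhb22 (-1.46) and Denn2b (-0.88) were lower. The sizes given for these 9 genes are against the mean of both other types. Ptpn13 lay at 7.55 to 8.20 in Type 2, 8.45 to 9.18 in Type 3 and 9.77 to 10.90 in Type 1. The smallest adjusted p of any gene in Type 2 minus Type 3 was 0.0117 (limma). Mamdc2, Foxn2 and Ldah were above every line of the other groups in 4 of 5 Type 2 lines, and Ptpn13 below them in 4 of 5. Tagln did not differ from the mean of the other types (-0.02 ± 0.70, adjusted p = 0.990), because Type 2 lay between them. Its levels were 12.27 to 13.24 in Type 1, 9.24 to 11.33 in Type 2 and 6.90 to 9.30 in Type 3.

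Of 30 genes induced by type I interferon, 0 rose and 2 fell in Type 2, with 29 of 30 differences negative (median -0.46). The list passed in camera (adjusted p = 0.00135) but not with an estimated correlation (adjusted p = 0.845), with fry (adjusted p = 0.238) or without the line Type_2 5 (adjusted p = 0.0869), and adjusted over the list alone 0 genes passed in limma. Rsad2 fell by 2.39 (adjusted p = 0.0384) and Ifit2 by 1.25 (adjusted p = 0.0467). Ifit1 (-0.97, adjusted p = 0.0712) and Mx1 (-2.40, adjusted p = 0.0819) did not pass; Mx1 did without Type_3 4 (adjusted p = 0.0409) or Other 7 (adjusted p = 0.0327), with the 16 lines of the 3 types alone (adjusted p = 0.0209) and with array weights (adjusted p = 0.00383). The 3 study markers, a list that is not independent evidence because it was chosen on these lines, had 0 higher and 1 lower (adjusted over the list alone 0 and 2; adjusted p = 0.0332 in camera, adjusted p = 0.113 with an estimated correlation, adjusted p = 0.0506 without Type_2 5, adjusted p = 0.0525 with depot in the model). The mesothelial list had 1 higher and 11 lower of 15 (adjusted over the list alone 1 and 11; adjusted p = 6.14e-14, and adjusted p = 0.0184 with an estimated correlation), against a mean that includes Type 1.

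The Type 3 lines had high Scara5, a scavenger receptor that binds ferritin, at 9.72 ± 1.42 (n = 8) against 5.38 ± 1.21 in Type 2 and 4.45 ± 0.72 in Type 1 (4.81 ± 0.83, adjusted p = 0.000244). Sned1 (4.53 ± 0.51), the chemokine receptor Ackr3 (3.66), Pla1a (3.54), Plpp3 (3.41), the homeobox gene Prrx2 (3.22), the growth factor Gdf10 (3.20) and Sparcl1 (3.14) rose too. These 7 are also low in Type 1 and did not pass in Type 2 minus Type 3: Sned1 -2.37, Ackr3 -2.11, Pla1a -1.06, Plpp3 -0.85, Prrx2 -1.51, Gdf10 -1.28 and Sparcl1 -2.49 (adjusted p from 0.0712 to 0.325). Grb10, an adaptor of the insulin receptor, averaged 4.12 ± 1.42 against 11.64 ± 0.19 in Type 1 and 6.51 ± 2.72 in Type 2 (-4.95 ± 0.91, adjusted p = 0.000457). Zic1 fell by 4.63 (adjusted p = 0.000125) while ranging widely within Type 2 (5.28 ± 3.40). It was high in Type_2 2 (8.81) and Type_2 4 (9.19), while the other Type 2 lines (2.67 to 2.90) lay in the range of Type 3 (2.62 to 2.90). Neither Grb10 nor Zic1 is among the genes named below that differed from both other types. Stk26, Krt18, Lrrn4, Upk3b, Gabra4 and Cd200, with differences from -4.19 to -3.65, completed the named genes, and Wt1 fell by 3.22. All of these are high in Type 1, which is part of the mean compared against. Wt1 did not pass in Type 2 minus Type 3. Smooth muscle contractile genes were lower, with 0 higher and 9 lower of 16 (adjusted over the list alone 1 and 9), in camera at adjusted p = 0.00284 and at adjusted p = 0.952 with an estimated correlation. Tagln fell by 3.46 ± 0.63 (adjusted p = 0.000427), Smtn by 1.39, Pdlim7 by 1.02 and Vcl by 0.88. The list holds the study marker Tagln. Mesothelial genes had 0 higher and 11 lower of 15 (adjusted over the list alone 0 and 11; adjusted p = 2.27e-13, and adjusted p = 0.0222 with an estimated correlation), against a mean that includes Type 1; the list did not pass in Type 2 minus Type 3 (adjusted p = 0.568). Mx1 did not pass (1.26 ± 0.79, adjusted p = 0.261), but did with array weights (adjusted p = 0.0062).

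Of the 12307 genes, 3133 changed in Type 3 (1460 higher, 1673 lower; 1665 and 1466 with each array centred on its median). Of these, 30 differed from both other types, 15 in each direction; this set too rests on the Type 2 minus Type 3 calls, which fell from 47 to 0 without Type_2 1 and are given by left-out line below. Higher were Scara5, the ligand Wnt16 (2.63 ± 0.46), the enzyme Gda (2.50), Rspo3 (2.05), Ttc39c (1.89), Gstt1 (1.75), the collagen Col14a1 (1.60) and the Wnt receptor Ror2 (1.40). Lower were the desmosome gene Pkp2 (-2.75 ± 0.31), Raph1 (-1.54), Ajuba (-1.28), Irak2 (-1.21), Lrrfip1 (-1.10), Tnfrsf12a (-1.02), Fkbp11 (-0.82) and Ifrd1 (-0.81). These sizes too are against the mean of both other types, not against each alone.

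Set directly against each other, Types 2 and 3 differed in 47 genes, 25 higher in Type 2 and 22 higher in Type 3. Pkp2 was higher in Type 2 by 2.36 (adjusted p = 0.0117) and Scara5 lower by 4.35, as -4.35 (adjusted p = 0.045). Neither Tagln (2.29, adjusted p = 0.125) nor Mx1 (-2.44, adjusted p = 0.168) nor Wt1 (-0.41, adjusted p = 0.479) passed. Smooth muscle contractile genes were higher in Type 2 (median 0.56, adjusted p = 0.000114) and type I interferon genes lower (median -0.33, adjusted p = 0.0137), both at adjusted p = 0.934 with an estimated correlation. The count rests on single lines. It was 0 without Type_2 1, 1 without Type_3 1, 5 or 8, 2 without Type_2 2 or 3 or Type_3 2, 8 without Type_1 3, 9 without Type_3 4 or 6, 13 without Type_2 4 or Type_1 2, 14 without Other 3, 15 without Type_3 3, 19 without Type_2 5, 25 without Type_3 7, 29 without Type_1 1, 101 without Other 4 and 195 without Other 7.

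The correlation of gene-centred profiles was 0.308 on average between lines of the same type and -0.203 between lines of different types, a difference of 0.51 (16 lines, one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Within Types 2 and 3 alone the difference was 0.283 (13 lines, permutation p = 0.00079). The types were formed by clustering of expression data, which favours a higher correlation within types. The permutation p-values for type are therefore not evidence that the types exist. For depot over 23 lines it was 0.061 (permutation p = 0.0451), a test that does not account for type, while all 3 Type 1 lines are PGF.

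In the 7 Other lines Cxcl9, an interferon-gamma-induced chemokine, averaged 12.69 ± 0.62 against 8.18 ± 1.28, 10.49 ± 1.49 and 10.28 ± 2.75 in Types 1, 2 and 3 (3.04 ± 0.82, adjusted p = 0.0311). Apod rose by 3.00 (adjusted p = 0.00811), Ccl8 by 2.61 (adjusted p = 0.00346), Ackr3 by 2.50 and Adm by 2.46. Lower were Zic1 (-3.00), Stk26 (-2.55), Lrrn4 (-2.47), Krt18 (-2.38) and Upk3b (-2.32), genes high in Type 1. Cxcl9 no longer passed without Other 1, 2, 4 or 6 or Type_1 1 or 3 (adjusted p from 0.0504 to 0.0703), nor with array weights (adjusted p = 0.0635). In total 705 genes changed (308 higher, 397 lower; 377 and 343 with each array centred on its median), 455 without Other 2 and 1267 without Other 7. Without the 3 Type 1 lines 1 gene passed, Megf10 (-1.59, adjusted p = 0.029, named after its value was seen), with 1138 at an unadjusted p below 0.05. The values were then 2.31 for Cxcl9, 2.11 for Apod, 1.12 for Ccl8, 1.12 for Ackr3, 0.76 for Adm and -1.18 for Zic1, and 0 of these 6 passed in limma (adjusted p from 0.333 to 0.665). Of the 8 lists that passed, the type I interferon, interferon-gamma, class I antigen presentation and inflammatory lists still passed in camera without the Type 1 lines.

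Of 30 type I interferon genes, 2 rose in Other and 0 fell, and 12 rose adjusted over the list alone; Ifit1 rose by 1.02 and Mx2 by 0.87. The list passed in camera (adjusted p = 3.58e-10; adjusted p = 0.561 with an estimated correlation). Interferon-gamma genes had 1 higher and 0 lower of 20 (adjusted over the list alone 1 and 0; adjusted p = 0.0241, adjusted p = 0.807 with an estimated correlation), with Cxcl10 at 1.38 (adjusted p = 0.0813); the call was lost without Other 2 (adjusted p = 0.0648) or Other 4 (adjusted p = 0.0518). Class I antigen presentation genes had 0 higher and 0 lower of 13 in limma, also adjusted over the list alone, with 13 of 13 differences positive (adjusted p = 0.04, adjusted p = 0.807 with an estimated correlation); the call was lost without any of Other 2, 3, 4 or 6, Type_2 5 or Type_1 2 or 3 (adjusted p from 0.0529 to 0.121). Inflammatory mediators had 2 higher and 1 lower of 19 (adjusted over the list alone 4 and 1; adjusted p = 0.00158, adjusted p = 0.561 with an estimated correlation, adjusted p = 0.0891 without Other 6). Ccl7 rose 2.84-fold and Ccl2 1.99-fold, and Il33 fell by 1.37.

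Subcutaneous-type patterning genes had 2 higher and 0 lower of 5 in Other (adjusted over the list alone 3 and 0; adjusted p = 0.00869, adjusted p = 0.0699 with an estimated correlation), the homeobox gene Shox2 by 1.64 and the T-box gene Tbx15 by 1.25. Shox2 averaged 9.81 in Other, 10.06 in Type 3 and 4.95 in Type 1. Smooth muscle contractile genes had 0 higher and 1 lower of 16 (adjusted over the list alone 0 and 4; adjusted p = 0.0111, adjusted p = 0.728 with an estimated correlation, adjusted p = 0.0812 without Other 6). Smtn fell by 0.74. The line Other 7 ran the other way, with the highest smooth muscle contractile score of the 23 lines (1.84, against -1.07 to 0.20 in the other 6 Other lines). Oxidative phosphorylation genes had 0 of 30 called by limma in either direction, also adjusted over the list alone, with 26 of 30 negative and a median of -0.07 (adjusted p = 0.0262, adjusted p = 0.718 with an estimated correlation). That call was lost without Other 2, Other 4, Type_1 2 or Type_1 3 (adjusted p from 0.0591 to 0.16). Without the 3 Type 1 lines the patterning list (adjusted p = 0.276), the smooth muscle list (adjusted p = 0.16) and the oxidative phosphorylation list (adjusted p = 0.0561) did not pass. Mesothelial genes had 0 higher and 10 lower of 15 (adjusted over the list alone 0 and 11; adjusted p = 5.47e-15, adjusted p = 0.013 with an estimated correlation); without the Type 1 lines they leaned the other way (adjusted p = 0.654).

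**Figure D2:**
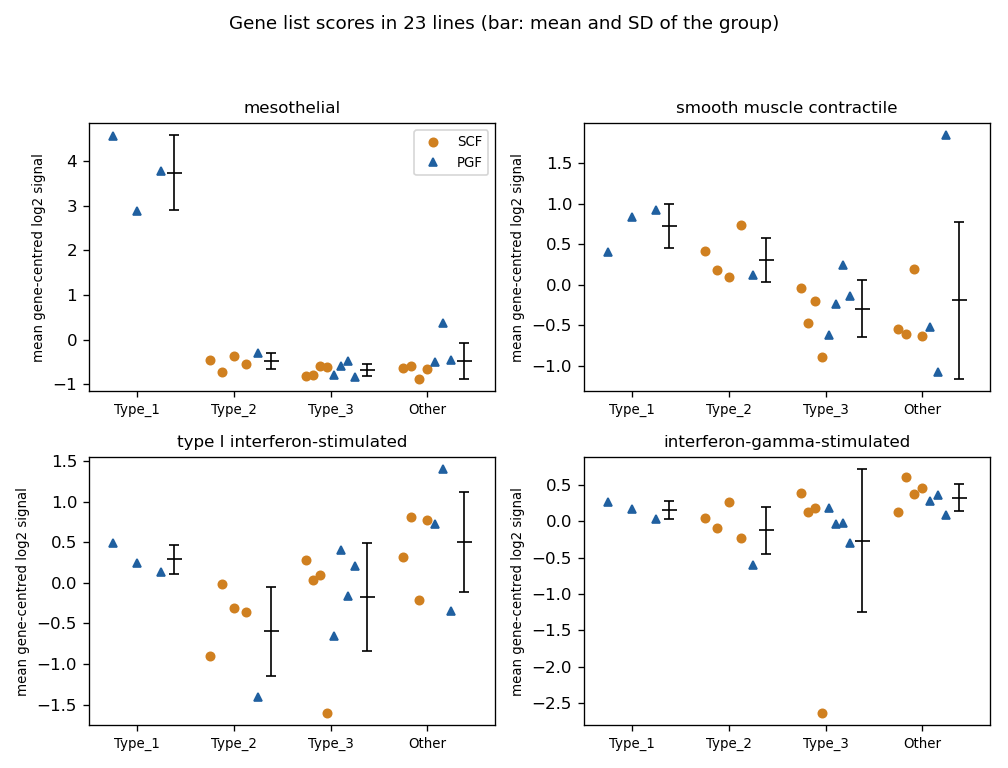
Each point is the score of a gene list in 1 line, the mean of its gene-centred log2 signals, for 4 lists in separate panels with the 4 groups on the horizontal axis; orange circles are SCF lines, blue triangles PGF lines, and the bar gives the mean and SD of the group. The mesothelial score averaged 3.73 ± 0.84 in Type 1 and below 0 in the other groups, and 1 Type 3 line lies at -2.64 in the interferon-gamma panel.

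Whether depot of origin left a mark within the groups was tested with type in the model. The types were formed by clustering of expression data and all 3 Type 1 lines are PGF. A depot difference that runs through the types is therefore not tested by this fit. No gene passed between PGF and SCF lines (limma, 0 of 12307; 1034 at an unadjusted p below 0.05, 615.4 by chance). The smallest adjusted p was 0.426. The genes with the smallest p were Zswim7 (0.42 ± 0.09), Apmap (0.49) and Adamts4 (0.62) on the PGF side and the mitochondrial gene ND5 (-0.53 ± 0.11), Trim3 (-0.34) and Asap1 (-0.34) on the SCF side. No patterning gene passed. Tbx15 differed by -0.56 ± 0.34 (adjusted p = 0.656), Wt1 by 0.42 (adjusted p = 0.637), Shox2 by 0.16, Sfrp2 by -0.02, Hoxc9 by -0.06, Hoxc10 by 0.08, Nr2f1 by 0.16, Gpc4 by 0.01, Thbd by -0.35, Hoxa5 by 0.23 and Hoxc8 by -0.27.

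In PGF minus SCF, 5 lists leaned to the PGF side in camera and none held with an estimated correlation. Inflammatory mediators, with Il6 at 1.36 ± 0.59 and Tnfaip3 at 0.95, had adjusted p = 0.00499 (adjusted p = 0.557 with an estimated correlation, adjusted p = 0.245 without Other 6). Glycolysis and lactate export genes, with Hk2 at 0.68 and Slc2a1 at 0.45, had adjusted p = 0.00792 (adjusted p = 0.557 with an estimated correlation, adjusted p = 0.0526 without Type_2 5). Hypoxia response genes, with Egln3 at 0.82 and Plod2 at 0.60, had adjusted p = 0.0269 (adjusted p = 0.557 with an estimated correlation) and did not pass without Other 3, 5 or 6, Type_3 6 or Type_2 5 (adjusted p from 0.0595 to 0.169). Cell cycle genes, with Cenpe at 0.40, had adjusted p = 0.0269 (adjusted p = 0.684 with an estimated correlation) and did not pass without Other 2, 4 or 5, Type_3 4 or 7 or Type_2 5 (adjusted p from 0.0621 to 0.173). Mesothelial genes had adjusted p = 0.0444 (adjusted p = 0.649 with an estimated correlation). They did not pass without Other 1, 2, 3 or 6, Type_3 1, 6 or 7, Type_2 2 or 5 or Type_1 2 (adjusted p from 0.0526 to 0.472). In each of these 5 lists limma called 0 members, over all genes and adjusted over the list alone.

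The differentiation score, from lipid staining after induction, was 2.00 ± 0 in Type 1 (n = 3), 2.80 ± 1.1 in Type 2 (n = 5) and 3.00 ± 0.756 in Type 3 (n = 8). The difference between Types 1 and 3 did not pass (exact permutation p = 0.0848, two-sided, adjusted p = 0.509 over 6 tests), nor did that between Types 1 and 2 (exact p = 0.464) or Types 2 and 3 (exact p = 0.751). Acidification averaged 3.33 ± 1.15, 3.00 ± 1.41 and 2.75 ± 0.886 (exact permutation p from 0.509 to 0.821). Other, which was not in these tests, had the lowest acidification mean at 1.86 ± 1.46, and a differentiation mean of 2.71 ± 0.756 (n = 7). By depot, the differentiation score was 2.82 ± 0.874 in PGF (n = 11) and 2.67 ± 0.778 in SCF (n = 12; permutation p = 0.8), and acidification 2.36 ± 1.29 and 2.83 ± 1.27 (permutation p = 0.418, adjusted p = 0.8). The scores were unrelated to each other over 23 lines (r = 0.0288, permutation p = 0.918; rho = 0.0268, permutation p = 0.9). Without Type_3 3 and Other 2 r was -0.016. These are the first, in order of deposition, of many lines tied in distance from the median differentiation score. Leaving them out is thus no check against extreme lines. Within SCF r was 0.307 and within PGF -0.202.

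No gene followed the differentiation score in limma (0 of 12307; 1331 at an unadjusted p below 0.05, smallest adjusted p = 0.159). Smallest p-values belonged to Bloc1s5 (0.17 ± 0.04 per point), Senp7 (0.44) and Crabp1 (1.03) with positive slopes and Pdzrn3 (-0.49 ± 0.09), Stx3 (-0.40) and Arhgef17 (-0.19) with negative ones. With type and depot in the model 2 genes passed, Csrnp1 (-0.44 per point, adjusted p = 0.0176) and Sparcl1 (1.21, adjusted p = 0.0361). Lists were negative with the score in camera for smooth muscle contractile genes (15 of 16 negative, adjusted p = 1.93e-08), interferon-gamma genes (18 of 20, adjusted p = 1.93e-08), mesothelial genes (14 of 15, adjusted p = 0.000407), type I interferon genes (25 of 30, adjusted p = 0.000918) and class I antigen presentation genes (13 of 13, adjusted p = 0.000918). Their values with an estimated correlation were adjusted p = 0.491, adjusted p = 0.491, adjusted p = 0.587, adjusted p = 0.829 and adjusted p = 0.587. Limma called 0 members over all genes, and adjusted over the list alone 7 smooth muscle and 3 interferon-gamma genes passed, among them Csrp1 (-0.43 per point) and Tpm1 (-0.40). Without the 3 Type 1 lines the mesothelial list did not pass (adjusted p = 0.406). Without Type_3 4 the class I list (adjusted p = 0.798) and the type I interferon list (adjusted p = 0.626) did not pass, and without Type_2 5 the type I list did not (adjusted p = 0.44).

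Over 16 relations of list scores with the 2 scores, 1 passed by rank. The smooth muscle contractile score had r = -0.551 with the differentiation score (permutation p = 0.00547, adjusted p = 0.0875) and rho = -0.616 (permutation p = 0.00237, adjusted p = 0.0379) over 23 lines. Without the 2 lines with the most extreme list scores r was -0.574. It was -0.461 within SCF (12 lines, permutation p = 0.133) and -0.688 within PGF (11 lines, permutation p = 0.018). The adipocyte differentiation score had r = 0.327 with the differentiation score (permutation p = 0.128, adjusted p = 0.518). Within SCF r was 0.0641 (permutation p = 0.842) and within PGF, which holds all Type 1 lines, 0.704 (permutation p = 0.0209, unadjusted).

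No gene followed acidification (limma, 0 of 12307; 650 at an unadjusted p below 0.05, smallest adjusted p = 0.895). The smallest p-values were those of Btbd6 (0.13 per point), Ebp (0.12) and Hr (0.10), and of Zfp106 (-0.09), Ampd2 (-0.20) and Slc35d1 (-0.17). In media acidification, cell cycle genes leaned negative (23 of 28, adjusted p = 0.000632), as did glycolysis and lactate export genes (15 of 19, adjusted p = 0.00984), with the glucose carrier Slc2a1 at -0.23 ± 0.06, and mesothelial genes positive (12 of 15, adjusted p = 0.0248), all at adjusted p = 0.893 with an estimated correlation. The mesothelial call was lost without Type_1 1 (adjusted p = 0.472), Type_1 2 (adjusted p = 0.194) or Other 3 (adjusted p = 0.0937). It was also lost without all Type 1 lines (adjusted p = 0.266). Adjusted over the list alone, limma called 1 glycolysis gene and 0 of the others.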

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

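The weighed tests below were chosen after the result was seen, except those of the interferon gamma receptor and its kinases and those of the chromosome shifts, whose predictions were written first.

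The Type 1 lines carry mesothelial transcripts and lack transcripts abundant in the other lines. Depot of origin was set against this through the 8 PGF lines outside Type 1. In mesothelial score they exceeded the 12 SCF lines by 4.3% of the gap of 4.37 between Type 1 and SCF. PGF origin thus did not come with a high score in every line. The types were formed by clustering of expression data, which tends to leave lines without this profile outside Type 1. A part for depot is therefore not decided by this comparison, and all 3 Type 1 lines are PGF. RNA quality is argued against by 2 Type 1 lines with an ordinary actin ratio whose score lay above all 20 other lines. A mixture of mesothelial cells with a large share of the common kind is argued against by 18 genes. These lay above 10 log2 in the other lines and at least 4 log2 lower in Type 1, such as Fgf7 (11.73 and 5.98), Plpp3 (12.44 and 6.74) and Ptn (12.17 and 7.96). They were picked by the drop of the mean of the 3 lines, so a small share, or a larger one in a single line, is not excluded. Type_1 2 had the lowest mesothelial score of the 3 (2.88). Fgf7 was highest of the 3 in Type_1 2 (7.77) and S1pr3 in Type_1 3 (6.01). A biological source, growth of these lines from mesothelial cells of perigonadal fat, was not tested here.

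Type_3 4 had the lowest interferon-gamma score, -2.64 against -0.30 to 0.39 in the other Type 3 lines. RNA quality is argued against, since other lines with an actin ratio at least as high had scores no lower than -0.60. A lower interferon gamma signal was not tested independently: 90.9% of the members of the interferon-gamma and class I antigen presentation lists (30 of 33) were lowest of all 23 lines there, with Gbp2 at 10.55 and Cd74 at 6.43, but these lists are the ones that singled the line out. Loss of receptor or kinase transcripts stays undecided, as Jak2 was -0.45 from the next lowest line, while Ifngr1 (8.91), Ifngr2 (8.20) and Jak1 (11.54) were not low. The same line also had a lower chromosome 19 (-0.27) in the scan below, and whether this bears on Jak2 or the score was not tested. What lies behind the low score is left open.

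In a scan for shifts of whole chromosomes in single lines, whose level and minimum shift were chosen after seeing the data, of 460 pairs of line and chromosome over 5622 genes, 146 had an adjusted p below 0.05 (10000 permutations of gene labels, which treat neighbouring genes as independent). Among these, 15 shifted by at least 0.15 log2 (adjusted p = 0.000582 each), 11 lower and 4 higher, in 8 lines; in Type 1, chromosome 14 of Type_1 2 was at 0.13 with that adjusted p. The shifts were chromosome 16 (0.27) and 15 (-0.21) in Other 5; 9 (-0.25), 17 (-0.22) and 7 (-0.18) in Other 6; 3 (0.27) in Other 7; X (-0.26) in Other 1; 5 (-0.20) in Type_2 5; 19 (-0.27) and X (0.16) in Type_3 4; 8 (-0.20) in Type_3 5; 14 (-0.22), 7 (-0.17), 12 (-0.16) and 18 (0.15) in Type_3 7. Gained or lost chromosomes in part of the cells may account for them. By gene order, 93.3% shifted in both the first and the second part, the exception being X in Other 1. By level, 93.3% shifted among both lower and higher expressed genes, the exception being X in Type_3 4. Both splits reuse the genes that gave the calls, which favours agreement. Only genes above 8 log2 entered the scan, so intensity-dependent bias is not decided by the split by level. No count of chromosomes was analysed here.

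Single lines far from the rest of their group were sought over 25 lists and 158 genes. Of 549 groups of lines, 78 results stood apart, where 1 in 20 independent groups would be 27.5. Most of the genes were named from these data, and lists and genes overlap, so 27.5 is not a chance expectation here. Of the 69 results for single genes, 26 came from Type_3 4. Among list scores the following stood apart: study markers in Other 1 at -1.14 (others -0.14 to 0.40), interferon-gamma-stimulated in Type_3 4 at -2.64 (others -0.30 to 0.39), MHC class I presentation in Type_3 4 at -1.18 (others -0.06 to 0.13), mesothelial in Other 6 at 0.37 (others -0.88 to -0.45), adipocyte progenitor in Type_2 3 at -0.60 (others -0.14 to -0.07), cell cycle in Type_3 4 at -0.56 (others -0.14 to 0.17), extracellular matrix in Type_2 4 at 0.41 (others 0.09 to 0.17), insulin and IGF signalling in Type_2 3 at -0.81 (others -0.31 to -0.14), macrophage and leukocyte in Type_3 4 at -0.67 (others -0.09 to 0.27).

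Single genes stood apart as log2 levels. Type_3 4 stood apart in Dcn at 12.72, Raph1 at 7.66, Dhx58 at 7.48, Socs1 at 5.32, H2-K1 at 13.11, H2-D1 at 12.82, H2-M3 at 9.83, ND5 at 12.74 and Gpc4 at 9.84. It also did in Pgk1 at 11.49, Aurkb at 8.08, Il6 at 3.83, Arhgef17 at 7.26, Zbp1 at 7.41, Parp14 at 8.63, Xaf1 at 10.21, Bst2 at 9.63 and Cd274 at 5.19. It also did in Irf8 at 4.64, Gbp2 at 10.55, Gbp6 at 9.42, Nlrc5 at 8.70, Tapbp at 10.10, Erap1 at 7.46, Psme1 at 10.92 and Pgam1 at 10.13. Other 7 stood apart in Pla1a at 8.58, Sncg at 6.31, Col6a3 at 7.29, Grb10 at 9.32, Lrrfip1 at 10.50, Atp5pb at 12.40, Il33 at 5.79, Sfrp2 at 3.51 and Csrp1 at 11.29. It also did in Tpm1 at 12.85. Other 6 stood apart in Stk26 at 6.44, Krt18 at 6.11, Lrrn4 at 4.37, Upk3b at 7.08, Bmp4 at 6.18, Upk1b at 7.20, Zbp1 at 10.88 and Gata4 at 5.86. Type_2 5 stood apart in Adm at 8.59, Smtn at 6.51, Atp5pb at 12.36, Zswim7 at 8.54 and Kif20a at 10.41. Type_2 4 stood apart in Ptpn13 at 8.20, Col14a1 at 5.18 and Hr at 6.05. Type_3 7 stood apart in Grb10 at 7.61, Cnn1 at 7.89 and Zfp106 at 10.06. Type_3 3 stood apart in Stk26 at 3.51 and Ido1 at 6.07. Type_2 3 stood apart in S1pr3 at 9.21 and Gda at 7.66. Type_3 1 stood apart in Pcdhb22 at 6.15 and Lif at 4.08. Type_2 1 stood apart in Gstt1 at 6.12 and Tpm1 at 11.90. Type_2 2 stood apart in Tbx15 at 9.45 and Hoxa5 at 7.19. Type_3 2 stood apart in Slc17a6 at 6.62. Other 1 stood apart in Mamdc2 at 4.96. Type_3 6 stood apart in Il33 at 4.86. Other 5 stood apart in Stx3 at 9.00.

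The slope of the visceral-type patterning list on the differentiation score differed between depots, with -0.49 per point in PGF minus SCF (adjusted p = 0.0346 in limma over 25 lists, for this 1 of 3 such tests). All 3 Type 1 lines are PGF, have a differentiation score of 2 and hold the highest values of this list (0.64 to 0.93), so depot and Type 1 are not separated here. No gene passed in the 3 tests of such differences (0 in limma; 956, 1394 and 1039 at an unadjusted p below 0.05).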

How the results depend on the processing

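The tests named here as added were chosen after the result was seen. Over single genes, lists and correlations 4852 values were recomputed. Of these, 4715 kept their side of the threshold, 127 no longer passed, 5 passed anew and 5 were counted as changed in direction. Changes of sign in genes that passed in neither fit were not counted as such. All 5 counted changes of direction came from leaving the 3 Type 1 lines out of the Other comparison (added): Stk26 0.26, Lrrn4 0.22, Krt18 0.36, Upk3b 0.30, and the mesothelial list (adjusted p = 0.654). By construction that contrast no longer holds the lines in which these genes are high, and it gave 1 gene and 5 lists. Of 438 counts and summary values, 384 stayed within 1.5-fold and 54 moved.

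Counts for Types 1, 2, 3 and Other were 7520, 2435, 5539 and 1232 with all probe sets, where more features are tested. With array weights the first 3 were 7073, 3175 and 5302; the cause was not tested. A 2-fold minimum left 1317, 453 and 642 and both pairwise contrasts (added) 2616, 9 and 30, since both ask for more. Type and depot in the model gave 2 genes for the differentiation score; the cause was not tested. Leaving out each line gave 2708 to 4267, 889 to 1559, 2560 to 3347 and 455 to 1267 genes, and 0 to 0 for depot and both scores. For lists those ranges were 1 to 3, 1 to 5, 2 to 2, 5 to 10, 1 to 8, 4 to 6 and 2 to 5, in the order Types 1, 2, 3, Other, depot, differentiation and acidification.

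Lists passing in Type 1 were 10 with fry and 2 with depot in the model. In Type 2 they were 1 with an estimated correlation and 6 with fry, in Type 3 1 and 6, in Other 1 and 3, and in depot and both scores 0 and 0. An estimated correlation allows for members that move together, and fry asks whether members move at all; for depot in the model the cause was not tested. Cd53 in Type 2 and Cxcl9 in Other were the single genes most often lost. Mx1 passed in Type 2 (adjusted p = 0.00383) and Type 3 (adjusted p = 0.0062) with array weights.

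No paired analysis was possible because replicate numbers only name lines and no label joins single lines across groups one to one. The number in the clone name is shared by several lines; with it in the model (added) 3634, 1030, 2777 and 600 genes passed for Types 1, 2, 3 and Other, and 0 for depot. Values without an offset, foreseen as a variant for linear data, were not run separately, because the values were already log2. No detection calls were used here, so values under the table median of 5.13 have an unknown distance from background.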

Other observations

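Tests against other splits of the lines were chosen after the result was seen. In Type 1, 5 insulin and IGF signalling genes rose and 5 fell of 18 (adjusted over the list alone 5 and 5; camera adjusted p = 0.93). The binding protein Igfbp2 rose by 6.83 ± 0.49 (n = 3 against 5 and 8 lines, adjusted p = 4.14e-10, limma), the growth factor Igf1 by 4.41 and the insulin receptor adaptor Grb10 by 6.33, while the binding protein Igfbp5 fell by 4.03. Adipocyte progenitor genes split alike, with 6 higher and 6 lower of 24 (adjusted over the list alone 7 and 7; camera adjusted p = 0.347, and as lower with fry at adjusted p = 0.00295). The proteoglycan Dcn rose by 6.00 and the surface glycoprotein Cd34 by 3.30, and the zinc finger gene Zfp423 fell by 3.27 and the growth factor receptor Pdgfrb by 2.46. Of the inflammatory mediators, 4 rose and 3 fell of 19 (adjusted over the list alone 4 and 3; camera adjusted p = 0.798), among them Saa3 (5.98) and Il33 (4.14), which rose, and Cxcl5 (-4.17), which fell. These genes were picked after their values were seen.

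Each count was set against 100 splits of the lines, the real one included. For Type 1 the real count of 4042 was reached by 1 split, itself, with 515 the highest other. The same held for Type 2 (1353, 1 split, highest other 1138), Type 3 (3133, 1 split, highest other 215) and Other (705, 1 split, highest other 3), but the groups had been formed by clustering such data, which favours the real split, so these 4 counts do not show whether chance can be excluded. At an unadjusted p below 0.05, depot (1034) was reached by 9 splits with a highest other of 1796, the differentiation score (1331) by 10 with 2623, and acidification (650) by 43 with 2270, so chance cannot be excluded for these 3.

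Eif2s3y, a gene of the Y chromosome, was at 3.19 in Other 1 and between 9.19 and 10.54 in the other 22 lines, while Uty (6.91) and Kdm5d (6.88) in that line lay within the range of the others.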
